A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

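Genomic DNA of BY4741 cells grown in rich medium was made into a CPD-seq library before irradiation. Per the labels' protocols, DNA pieces received an adaptor and their free 3′ ends were blocked. T4 endonuclease V followed by APE1, an abasic endonuclease, then opened the strand at dimers, and the new 3′ end took a second adaptor. Reads that do not come from dimers can arise wherever a 3′ end escapes the block or another lesion is cleaved, so the unirradiated library measures the background of the assay. Amplification and any GC preference of the library act on every read count reported here.

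The submitters' processing notes name Bowtie2 2.2.6, SAMtools, bedtools and the genome build sacCer3, with no role, order or option. The deposited table has 1 line per read with an interval of 2 bases, a strand and, in its other columns, a read name and a score; no line is a count per position. The deposited score is a whole number per read from 0 to 42, read here from its values as the aligner's mapping quality, since the sources used here do not name it. Positions of the other deposited columns are coordinates, not signal values. From the values, the interval lies just 3′ of the sequenced fragment on its strand, and all 16 dinucleotides occur. Of 8297422 reads, 74.5% had a score of at least 20 and 19.1% a score of at most 1. The 32 reads whose interval runs past a chromosome end were left out. Chromosome names and lengths of the files' build matched the reference genome used for sequence and annotation.

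Reads were counted per strand position. Unless stated, ratios use nuclear positions whose 40 bases 5′ of the cut occur once in the reference, outside the ribosomal DNA on chromosome XII from 451575 to 489469; 93.9% of nuclear strand positions were uniquely alignable. The expected count is the sum over positions of the genome-wide read rate of each dinucleotide. Ratios between regions are ratios of observed to expected reads. The transcribed strand of a gene is the template strand, and gene models hold coding sequence without UTRs. Origins, centromeres, tRNA genes, Ty elements and long terminal repeats came from the annotation. Intervals have a level of 95%, and a count of 0 is given against a floor of 3 counts.

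Genes were named by a rule. Among nuclear protein-coding genes with at least 100 expected reads and at least 80% uniquely alignable positions, these were the 10 highest and 10 lowest ratios, the 5 largest and 5 smallest strand ratios among genes with at least 50 expected reads per strand, the highest and lowest member of each of 11 fixed lists, and URA3, LEU2, MET15 and HIS3. Genes with at most 3 reads on both strands have no strand ratio and were left out of that ranking, a choice made after the data were seen. Genes that overlap another gene were not ranked by strand ratio either. The lists' medians under the dinucleotide expectation were placed among 10000 random lists of the same size, as a description of this library. The random lists were matched on coding length and GC content in 5 bins each. MEL1 is absent from the annotation used here, and 1 repair gene was listed under both of its names.

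Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The counting of genes was tested on simulated data, with Poisson counts drawn from the expectation for all positions and 200 genes changed. The 50 genes raised 2-fold came back at a median of 1.98, the 50 genes lowered to 0.5 at 0.501, and the 100 genes with a strand ratio of 1.5 at 1.51. The 5220 unchanged genes had a median of 0.994. Because the counts came from the expectation fitted to this library, the simulation checks the counting only and not the expectation. It held neither the spread beyond Poisson counts nor the trend with GC content of the real library.

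The gene rule, the lists and a set of alternatives were chosen before the data were examined. These alternatives counted each strand position once, left out the 0.1% of covered positions with the most reads, used all nuclear positions with repeats, used no sequence term or a tetranucleotide term, and changed window sizes and gene sets. Alternatives chosen after the data were seen used reads with a score of at least 20, added the GC content of the 200 bases 5′ of the cut in 20 classes, used the 8 bases around the cut (added once the tetranucleotide values were known), combined the 8 bases with GC content (added once each alone was known), restricted the origin strand difference to intergenic positions, and looked for the highest positions outside the ribosomal DNA. The loci of these positions are not reported here. Under an alternative, density medians of lists, and the densities of single genes given with the dependence on processing, are relative to its shift of the median gene. On the log2 scale this shift was -0.23 with repeats included and -0.051 under the GC-adjusted expectation. GC-adjusted ratios of single genes in the results are as computed, without that shift, and strand ratios carry no such shift anywhere. Leaving out a replicate was not possible with 1 library.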

Results

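The data are 1 CPD-seq library of budding yeast that was not irradiated. CPD-seq maps cyclobutane pyrimidine dimers, the main DNA lesion made by ultraviolet light, by turning each lesion into a strand end that can be ligated and sequenced. The strain was BY4741, a laboratory haploid of mating type a that carries deletions of URA3, LEU2, MET15 and part of HIS3, and the cells were in growth in rich medium. The series holds 8 samples, of which the No UV library is analysed here; the irradiated cells and the irradiated naked DNA are not analysed here. The library held 8297422 reads, of which 4132266 lay on the plus strand and 4165156 on the minus strand. With 1 library there are no replicates and no test between conditions. Intervals are 95% intervals for counting error only, exact Poisson for ratios to an expected count and Clopper-Pearson for shares and for ratios of 2 counts; PCR reads without molecular identifiers are not independent molecules. The spread over the 16 nuclear chromosomes is given as a description.

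The 3 auxotrophic markers that BY4741 lacks had 1 read or none. LEU2, an enzyme gene of leucine synthesis on chromosome III at 91324 to 92418, had 0 reads against 613 expected from its sequence. The floor of 3 counts gives a ratio of 0.00489, and the upper limit of the exact interval was 0.00601. MET15, listed in the annotation as MET17 on chromosome XII at 732542 to 733876, had 0 reads against 750.3 expected. Its floor ratio was 0.0040 and its upper limit 0.00492. URA3, an enzyme gene of uracil synthesis on chromosome V at 116167 to 116970, had 1 read against 452 expected, a ratio of 0.00221 with an interval of 5.6e-05 to 0.0123. HIS3, an enzyme gene of histidine synthesis on chromosome XV at 721946 to 722608, had 361 reads against 371 expected, a ratio of 0.973 with an interval of 0.876 to 1.08. Within HIS3, no read of either strand fell on 722289 to 722397. The plus strand alone was empty over 213 bp from 722289 to 722501, and the minus strand over 183 bp from 722215 to 722397. When the GC content of the sequenced fragment entered the expectation (called the GC-adjusted expectation from here on), the HIS3 ratio was 0.538. The gene YLR302C, at 732191 to 732553, overlaps MET17 only from 732542 on and had 40 reads against 202 expected.

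The mating type gene HMRA1, the silent copy of the a1 regulator on chromosome III at 293835 to 294321, had 277 reads at a ratio of 1.00. The MAT locus of an a strain holds the same sequence, which the alpha MAT locus of the reference lacks. Under the GC-adjusted expectation the HMRA1 ratio was 1.88, with an interval of 1.67 to 2.12. The alpha genes MATALPHA1 and MATALPHA2 have no uniquely alignable position in the reference, because HML holds the same sequence, and were not used to check the mating type.

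Without ultraviolet light the reads were not concentrated on pyrimidine dinucleotides, the sites where dimers form. TT, TC, CT and CC together took 25.2% of 6399366 nuclear reads, with an interval of 25.2% to 25.3%, and made up 26.8% of the genomic sites. The ratio of the 2 shares was 0.94. Reads per site relative to the mean were 0.989 for TT, 0.933 for TC, 0.897 for CT and 0.878 for CC. TT moved to 1.00 when each strand position was counted once. The purine steps AA, GA, AG and GG were at 0.988, 0.925, 1.01 and 0.876. The most used steps were CG at 1.14 and AT at 1.14. The 16 values therefore ranged from 0.876 to 1.14.

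The strongest base preference lay at the last base of the sequenced fragment, just 5′ of the assigned dinucleotide. There G was used at 1.41 times its genomic share and T at 0.733 times. At the first base of the dinucleotide the shares were 1.049 for A, 0.932 for C, 0.978 for G and 1.01 for T. Purine enrichment was 1.02 at that base, with an interval of 1.02 to 1.02, and 1.16 at the base before it. G was also above its genomic share 4 bases before the dinucleotide, at 1.20, and C 2 bases before it, at 1.19.

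**Figure D1:**
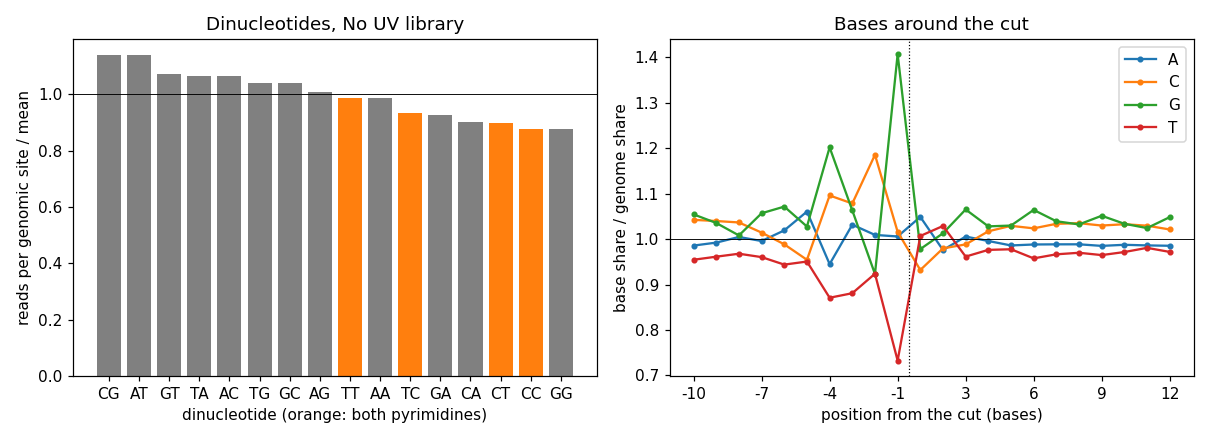
Left, reads per genomic site of each dinucleotide divided by the mean over all sites, with pyrimidine dinucleotides in orange; right, the share of each base among reads divided by its genomic share, by position from the cut, where 1 is the first base of the dinucleotide. The dinucleotides lie between 0.876 and 1.14, and G at the last base before the cut reaches 1.41.

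Over uniquely alignable nuclear positions outside the ribosomal DNA, read density rose with the GC content of the sequence next to the cut. Positions were put in 20 classes by the GC content of the 200 bases 5′ of the cut, the side on which the sequenced fragment lies. In the lowest class, with a mean GC content of 27.8%, reads were at 0.475 of the expected number. In the highest class, at 50.1% GC, they were at 2.12. This expectation was chosen after the data were seen, and its values are given with many of the comparisons below.

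**Figure D2:**
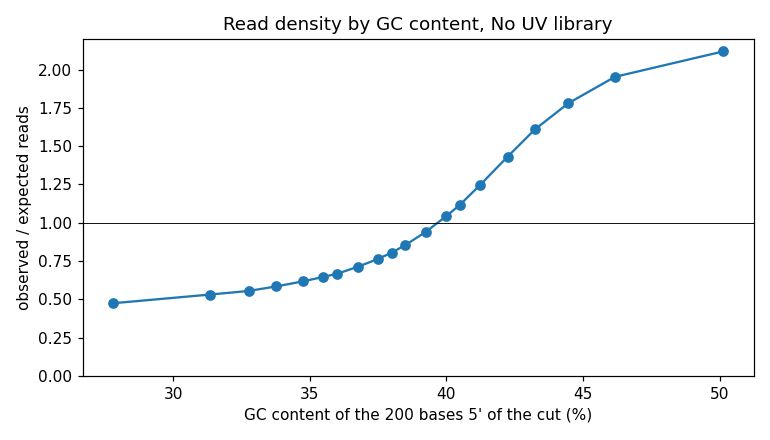
Observed over sequence-expected reads (vertical axis) for 20 classes of positions by the GC content of the 200 bases 5′ of the cut (horizontal axis, mean percent per class). Density rises from 0.475 to 2.12.

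Mitochondrial DNA and ribosomal DNA, both present in many copies per cell, took large shares of the library. Mitochondrial DNA had 272311 reads, 3.28% of the total with an interval of 3.27% to 3.29%, and its 3175 reads per kb were 5.53 times the 574 reads per kb of the median nuclear gene. With each strand position counted once, the mitochondrial share was 1.91% and the ratio to the median gene 2.76. The 35S ribosomal RNA gene RDN37, which is present in 2 copies in the reference on chromosome XII (451575 to 458432 and 460712 to 467569), had 762931 reads. Its density was 96.9 times that of the median gene, and 2 times that value gives 194 units. Neither this ratio nor the mitochondrial one was adjusted for GC content, so neither can be read as a copy number. Counting each strand position once lowered the RDN37 ratio to 4.82, since positions in the repeat carry many reads. Of the reads in RDN37, 119 had a mapping quality of at least 20.

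Chromosome I had the highest read density of the 16 nuclear chromosomes and chromosome IV the lowest. Chromosome I, of 230218 bp, was at 1.14 times the mean of the 16, and chromosome IV, of 1531933 bp, at 0.89. The coefficient of variation over the 16 chromosomes was 7.34%. As observed over expected reads, the chromosomes ranged from 0.918 to 1.17. Under the GC-adjusted expectation this range was 0.955 to 1.08, with chromosome VI highest and chromosome IV lowest.

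Summed over whole coding sequences, the transcribed strand carried fewer reads than the non-transcribed strand. Under the dinucleotide expectation, but not the GC-adjusted one, the order was the opposite close to start codons. Over 5735 genes that overlap no other gene, the ratio of the 2 strands was 0.924, with a counting interval of 0.923 to 0.926. It was below 1 on 16 of 16 chromosomes, with an SD of 0.00564 over chromosomes and a range of 0.913 to 0.933. The ratio was 0.942 under the GC-adjusted expectation and below 1 on 16 of 16 chromosomes there too. Over the 5420 single genes with at least 50 expected reads per strand and no overlap with another gene, the median log2 ratio was -0.12. Its SD was 0.26, against 0.13 from counting error alone. In a profile around the start codons of 3592 genes of at least 1000 bp, the transcribed strand was the higher one in each 10 bp bin of the first 130 bp of the coding sequence, at 1.22 of the expected reads against 0.805 on the non-transcribed strand in the first bin. Under the GC-adjusted expectation the order turned in each of these bins, with 0.954 on the transcribed and 1.15 on the non-transcribed strand in the first.

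The genes with the largest strand ratios were short, at 204 to 372 bp, and so were those with the smallest, at 258 to 606 bp. YGL194C-A was at 2.51 (interval 1.60 to 4.04), YGR035W-A at 2.35, YIL134C-A at 2.34, YDL241W at 2.13 and VMA7, a subunit gene of the vacuolar proton pump, at 2.27. YGR035W-A was at 0.729 under the GC-adjusted expectation. The smallest ratios were those of YRB1, which encodes a Ran-binding protein of nuclear transport, at 0.348 (interval 0.265 to 0.452), YOR314W at 0.355, MRPL50, a mitochondrial ribosomal protein gene, at 0.406, SLO1 at 0.416 and CWC15, a splicing factor gene, at 0.421. LEU2 and URA3, with at most 3 reads on each strand, were given no strand ratio. YLR302C, at 12.7 from 37 reads against 3, was not ranked because it overlaps another gene.

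Intergenic sequence had fewer reads than coding sequence, and this difference turned when GC content was taken into account. The ratio was 0.838 with a counting interval of 0.836 to 0.839, below 1 on 16 of 16 chromosomes, with an SD of 0.0567 over chromosomes. Gaps between divergent genes were at 0.924 of coding sequence, gaps between tandem genes at 0.831 and gaps between convergent genes at 0.668. GC-adjusted, the intergenic to coding ratio was 1.04, above 1 on 15 of 16 chromosomes.

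The 150 bp upstream of start codons were also low relative to the first 1000 bp of coding sequence. The ratio was 0.816 with an SD of 0.0276 over chromosomes, and it was below 1 on 16 of 16 chromosomes. In the profile over 3592 genes, both strands together, the lowest bin lay 150 to 141 bp upstream, at 0.802 of the expected reads, and the highest 220 to 229 bp downstream, at 1.21. The GC-adjusted ratio was 1.00 and the same upstream bin was at 0.967. Reads that lay in the windows of 2 genes were counted for each, so the counting interval of 0.814 to 0.819 is too narrow.

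**Figure D3:**
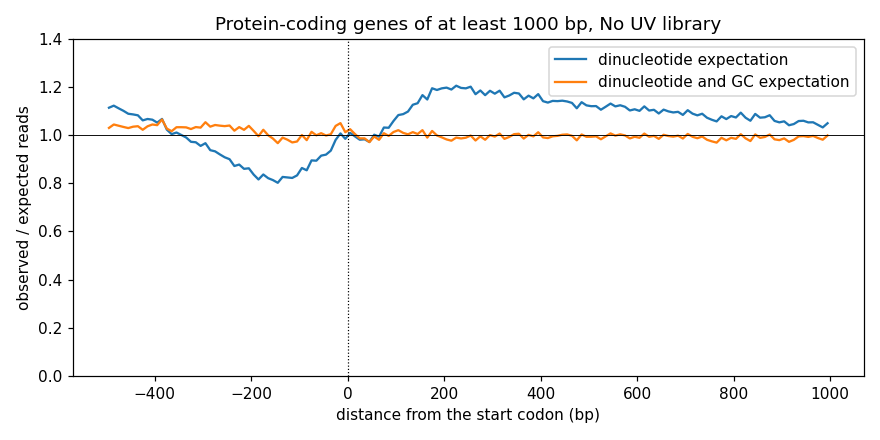
Observed over expected reads (vertical axis) in 10 bp bins around the start codon (horizontal axis, bp) of 3592 protein-coding genes of at least 1000 bp, with an expectation from dinucleotides (blue) and from dinucleotides and fragment GC content (orange). The blue line falls to 0.802 upstream and rises to 1.21 downstream; the orange line has its lowest upstream bin at 0.967.

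Positions within 5 kb of the 352 annotated replication origins had slightly more reads than positions more than 15 kb away. The ratio was 1.04 with a counting interval of 1.04 to 1.04, above 1 on 14 of 16 chromosomes, and the SD over chromosomes was 0.046. The difference from 1 was smaller than this SD, which describes the spread over chromosomes and not the error of the genome-wide ratio. The GC-adjusted ratio was 1.046 and above 1 on 16 of 16 chromosomes, with an SD of 0.0387. With repeats included, and thus the ribosomal DNA, it was 1.57; with a mapping quality of at least 20 it was 1.03 and above 1 on 8 of 16 chromosomes. Positions within 2 kb of an origin were at 0.964 of the expected reads and those from 2 to 4 kb at 1.054.

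Around centromeres reads were at 0.961 of the rest of the arms within 10 kb, below 1 on 14 of 16 chromosomes, with an SD of 0.095. The GC-adjusted centromere ratio was 1.06. Within 20 kb of chromosome ends the ratio was 1.04, above 1 on 8 of 16 chromosomes, with an SD of 0.152. The GC-adjusted telomere ratio was 1.09, above 1 on 15 of 16 chromosomes, with an SD of 0.0501. The telomere ratio was 0.858 when reads with a mapping quality below 20 were left out. Ty elements and long terminal repeats were at 0.712 of the rest of the nuclear genome over uniquely alignable positions, with an SD of 0.122, and at 1.03 over all positions. Over all positions that rest includes the dense ribosomal DNA, so these values have different denominators. The tRNA genes were at 0.804, with an SD of 0.117 and 15 of 16 chromosomes below 1. GC-adjusted, Ty elements were at 1.07 and tRNA genes at 1.15; with the 8 bases around the cut as well, tRNA genes were at 0.991.

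Between genes the density varied more than counting error allows. Over 5570 measured genes the SD of the log2 ratio of observed to expected reads was 0.56, against 0.064 from counting error, and 188 genes lay above 2 times and 85 below 0.5 times the expectation. Under the GC-adjusted expectation the SD was 0.28. The median ratio was 0.646 in the fifth of genes with the lowest GC content, at a median of 36.1%, and 1.70 in the fifth with the highest, at 44.8%. GC-adjusted, these medians were 0.897 and 1.07, so part of the trend remained.

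The 10 genes with the highest ratios had GC contents from 45.6% to 58.0%. They were YFR018C on chromosome VI at 2.58 (interval 2.45 to 2.71), HPF1, a cell wall mannoprotein gene, at 2.58, SHU1, a recombination gene, at 2.52, PHO4, the phosphate-response transcription factor gene, at 2.50, YJR146W at 2.49, PIR1, a cell wall protein gene, at 2.48, MIC10, a gene of mitochondrial cristae structure, at 2.48, YAT1, a carnitine acetyltransferase gene, at 2.46, SHR5 at 2.44 and IRC24 at 2.42. Their GC-adjusted ratios ranged from 1.19 for YAT1 to 1.55 for MIC10. Among the lowest 10, after LEU2, MET17, URA3 and YLR302C, came SPG3 at 0.335, LSM2, an RNA-binding protein gene, at 0.340, NMD4 at 0.380, ERG28, a gene of ergosterol synthesis, at 0.382, MIN6 at 0.402 and NVJ3 at 0.403. These 6 had GC contents from 26.3% to 39.1%, and their GC-adjusted ratios ran from 0.480 for ERG28 to 0.706 for MIN6.

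Of the 11 fixed gene lists, glycolysis had the highest median and the meiosis genes the lowest under the dinucleotide expectation, an order that changed under the GC-adjusted one. All 14 measured glycolysis genes lay above the expectation, with a median log2 ratio of 0.70, from HXK2, a hexokinase gene, at 1.15 to GLK1, the glucokinase gene, at 2.23; GC-adjusted, HXK2 was at 0.941 and GLK1 at 1.12. That median lay at percentile 59.8 of 10000 random lists matched on coding length and GC content. All 24 meiosis genes, which are silent in growth, lay below the expectation, with a median log2 ratio of -0.40, at percentile 84.3 of matched lists, from HOP2 at 0.466 to REC8, a meiotic cohesin gene, at 0.976. The GC-adjusted medians were 0.056 for glycolysis and -0.060 for meiosis, with subtelomeric families highest at 0.093 and core histones lowest at -0.083. Over the highest and lowest members of the 11 lists, GC-adjusted ratios ran from 0.594 for COX6 to 1.39 for DAN1.

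The respiratory chain, the core histones and the chaperones lay low among their matched lists under the dinucleotide expectation, the only one for which percentiles are given. The 28 respiratory chain genes had a median log2 ratio of -0.14 at percentile 0.19, from COX6, a cytochrome c oxidase subunit gene, at 0.487 to CYT1, the cytochrome c1 gene, at 1.85. The 6 measured core histone genes had a median of 0.00061 at percentile 1, from HTA2 at 0.659 to HHT1 at 1.32. The 14 heat shock and chaperone genes had a median of 0.24 at percentile 1.33, from HSC82, an Hsp90 gene, at 0.745 to HSP12 at 1.83. GC-adjusted, these medians were 0.020, -0.083 and -0.039. With a mapping quality of at least 20, the core histone median was -0.60 and HHT1 was at 0.858.

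The repair lists lay within the range of matched lists. The 23 nucleotide excision repair genes, whose products remove ultraviolet lesions, had a median log2 ratio of -0.18 at percentile 28.1, from RAD34 at 0.554 to RAD23, a damage recognition gene, at 1.83. This median was -0.016 under the GC-adjusted expectation and 0.0030 with the 8 bases around the cut and fragment GC content in the expectation. The 13 genes of base excision repair and photolyase had a median of -0.18 at percentile 20.1, from POL4 at 0.605 to NTG1, a DNA glycosylase gene, at 1.53, and a GC-adjusted median of 0.013. The 111 ribosomal protein genes were at -0.13 (GC-adjusted -0.030) and percentile 22.5, from RPS30B at 0.417 to RPS2 at 1.84. The 9 galactose genes were at 0.41 (GC-adjusted 0.052) and percentile 96.3, from GAL7 at 0.761 to GAL3 at 1.59. The 9 measured genes of subtelomeric families were at 0.023 and percentile 46.6, from COS12 at 0.529 to DAN1 at 2.36, and the 3 measured translation factor genes at 0.13 and percentile 10.0, from YEF3 at 0.985 to HYP2 at 1.48. GC-adjusted, the translation factor median was 0.072.

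On the strand ratio under the dinucleotide expectation, ribosomal protein and glycolysis genes lay high among matched lists. The 110 ribosomal protein genes had a median log2 strand ratio of -0.059 at percentile 99.6, where the matched lists had a median of -0.14. Under the GC-adjusted expectation their median was -0.10, below the median of -0.091 over all measured genes. The 13 glycolysis genes were at 0.045 and percentile 98.7, and the 9 genes of subtelomeric families at 0.062 and percentile 98.3. GC-adjusted strand medians of glycolysis and subtelomeric families are not given here, so their high place rests on the dinucleotide expectation alone. Nucleotide excision repair genes were at -0.18 and percentile 16.6, base excision repair and photolyase genes at -0.13 and percentile 45.4, and respiratory chain genes at -0.15 and percentile 47.3. Core histones were at -0.28 and percentile 22.0, chaperones at -0.18 and percentile 17.3, translation factors at -0.18 and percentile 38.7, galactose genes at 0.0031 and percentile 88, and meiosis genes at -0.062 and percentile 88.8. The core histone median turned to 0.042 and the chaperone median was -0.25 under the GC-adjusted expectation, and the meiosis median to 0.037 with the 8 bases around the cut.

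The reads fell on 5129992 distinct strand positions. The 1% of positions with the most reads took 13.6% of the reads. Over uniquely alignable nuclear positions outside the ribosomal DNA, 4557713 of 22662270 strand positions had a read, which is 81.7% of the number a Poisson distribution of the same mean would give.

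The 10 uniquely alignable nuclear positions with the most reads all lay on the minus strand of NTS1, the non-transcribed spacer of the ribosomal DNA on chromosome XII at 459797 to 460711. The highest, at 460407 to 460408, had 281 reads in the sequence AACAGTGGGGACATTTTTTTTT, and the next, at 460405 to 460406, had 259. NTS1 has 1 copy in the reference, where reads of many repeat units pile up, and 84.8% of its positions are uniquely alignable. RDN37 and the other spacer, NTS2, have no such position and could not enter this ranking. With reference copies summed, NTS1 was less dense than RDN37, at 0.846 of it on the minus strand and 0.583 on the plus strand. These densities, and the strand ratios that follow, were not adjusted for sequence or GC content. NTS1 had 29240 reads on the plus strand and 43691 on the minus strand, a ratio of 1.49. The same ratio was 1.29 for NTS2 and 1.03 for RDN37.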

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

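The alternatives with a mapping quality of at least 20, with fragment GC content, with the 8 bases around the cut or outside the ribosomal DNA were chosen after seeing the data. No paired analysis was possible because only 1 library was analysed. Among the main results, 218 values under an alternative stayed within their 95% interval, 81 left it and 18 were counted as crossing 1 (or 0 for log2 values). For single genes, dinucleotides with a purine and the origin strand difference, these numbers were 374, 143 and 5. A crossing was counted only where the main interval did not include 1 (or 0). Other changes of side are therefore counted among the values that stayed or left. For region ratios and shares the intervals are narrow at this depth, so leaving one can be a small change. Those of list medians are wide, such as -0.364 to 0.854 for the density of subtelomeric families. Staying within such an interval can therefore be a large change. Leaving out the 0.1% of covered positions with the most reads moved no main result it was run on out of its interval. The strand ratio stayed below 1 on 16 of 16 chromosomes and the genome-wide origin ratio above 1 under every alternative run. The cause was not tested unless stated.

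Of window and gene choices, the upstream ratio was 0.823 for divergent and 0.807 for tandem neighbours, the origin ratio 1.07 for 10 kb against more than 20 kb, the centromere ratio 0.891 at 5 kb, the telomere ratio 1.04 at 10 kb, the strand ratio 0.927 for genes of at least 1000 bp and the intergenic ratio 0.821 beyond 300 bp from start codons. The top 0.1% of positions took 3.63% of reads. Over reads of all scores, the highest position outside the ribosomal DNA had 29 reads.

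With each position counted once, the pyrimidine share was 25.6%, and CC, CT, TC and TT were at 0.898, 0.915, 0.948 and 1.00. The strand, intergenic, upstream, origin, centromere, telomere, Ty and tRNA ratios were 0.937, 0.862, 0.848, 1.04, 0.970, 1.03, 0.753 and 0.850. Chromosomes I and IV were at 1.11 and 0.909, purine enrichment at 1.01 at the first base and 1.13 before it, the mitochondrial share at 1.91% and the ribosomal DNA ratio at 4.82.

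With all nuclear positions, the pyrimidine share was 25.0%, and CC, CT, TC and TT were at 0.913, 0.905, 0.920 and 0.964. The strand, intergenic, upstream, origin, centromere, telomere and Ty ratios were 0.927, 0.931, 0.850, 1.57, 0.817, 1.16 and 1.03, and chromosomes I and IV were at 1.04 and 0.826. The ribosomal DNA, which holds origins, enters by construction. It also lies in the rest to which centromeres, chromosome ends and Ty elements are compared.

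With no sequence term, the intergenic and upstream ratios were 0.844 and 0.821. With tetranucleotides the strand, intergenic, upstream, centromere, Ty and tRNA ratios were 0.939, 0.851, 0.834, 0.966, 0.728 and 0.748.

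With a score of at least 20, TT was at 0.992, the intergenic, upstream, origin, telomere, Ty and tRNA ratios were 0.821, 0.808, 1.03, 0.858, 0.514 and 0.765, ribosomal protein genes were at -0.45, core histones at -0.60 and HHT1 at 0.858, purine enrichment was 1.02 and 1.16, the mitochondrial share 3.84% and the ribosomal DNA ratio 0.0163, since repeats have low scores.

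With fragment GC content, the strand, intergenic, upstream, origin, centromere, telomere, Ty and tRNA ratios were 0.942, 1.04, 1.00, 1.046, 1.06, 1.09, 1.07 and 1.15. The medians of ribosomal protein, glycolysis, nucleotide excision repair, meiosis and chaperone genes were -0.030, 0.056, -0.016, -0.060 and -0.039, and the log2 strand ratios of core histones and chaperones 0.042 and -0.25. The strand ratio of YGR035W-A was 0.729 and the density of HXK2 0.974. With the 8 bases, the strand, intergenic, upstream, centromere, Ty and tRNA ratios were 0.957, 0.866, 0.853, 0.972, 0.744 and 0.721, and the log2 strand ratio of meiosis genes 0.037.

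With the 8 bases and fragment GC content together, the strand, intergenic, upstream, origin, centromere, telomere, Ty and tRNA ratios were 0.971, 1.06, 1.04, 1.047, 1.07, 1.08, 1.08 and 0.991. The medians of glycolysis, nucleotide excision repair, meiosis and chaperone genes were 0.036, 0.0030, -0.045 and -0.044, and the log2 strand ratios of core histones and meiosis genes 0.041 and 0.036. The strand ratio of YGR035W-A was 0.721 and the density of HXK2 0.967.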

Other observations

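The tests of fragment GC content, of the 8 bases around the cut, of abasic sites and of the ribosomal spacer used measures or alternatives chosen only after results had been seen; for intergenic sequence and for the 8 bases, the bound was set before the tested value was known. The origin strand difference was added to the measures after the data were first seen, with its prediction written before its value was computed.

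Right of replication origins the minus strand took 50.5% of reads within 5 kb, left of them 49.6%, over 350 origins. The difference of 0.95 percentage points (bootstrap 95% interval over origins 0.599 to 1.26) has the direction that 3′ ends of unjoined Okazaki fragments would give. An expectation from the 8 bases around the cut left 0.805, with an interval of 0.516 to 1.09, which argues against base preference as the whole cause; over intergenic positions alone the difference was 0.717 (0.166 to 1.24). With fragment GC content in the expectation it was 0.184, with an interval of -0.152 to 0.484, and with the 8 bases as well 0.108 (-0.162 to 0.370), so the GC content of the fragment, which lies on opposite sides of the cut for the 2 strands, may account for it. Whether Okazaki fragments contribute cannot be told apart from this GC effect, since the remaining interval includes 0.

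The lower density on the transcribed strand was reduced but not removed by the sequence terms used. The ratio of 0.924 rose to 0.957 with the 8-base expectation and to 0.971 when fragment GC content was added. With an SD of 0.00591 over chromosomes, it stayed more than 1 SD from 1. That SD does not measure the error of the expectation. The same expectation left 1.06 for intergenic sequence, 1.04 upstream of start codons, 1.08 near chromosome ends and 0.991 for tRNA genes. Whether these terms are the whole cause therefore cannot be told. A longer sequence preference stays open. No biological explanation was tested.

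The lower density of intergenic sequence may come largely from GC content. The ratio of 0.838 became 1.04 with fragment GC content in the expectation, with an SD of 0.0133 over chromosomes. This lay more than 1 SD from 1, so the prediction set before the value was known was not met. The ratio lay on the other side of 1, with no deficit left. The reading that this does not exclude GC content as the cause of the deficit was chosen after the value was seen. The GC-adjusted expectation was fitted to this same library, so it would also absorb a difference between intergenic and coding sequence that goes with GC content. Whether GC content is the cause therefore cannot be told. The excess that this expectation leaves stays open. No biological explanation was tested.

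Cleavage at depurinated sites would raise purines at the first base of the dinucleotide, where enrichment was 1.02, against 1.16 at the base before it. Spacer NTS1 had 0.846 of the RDN37 density on the minus strand and 0.583 on the plus strand with reference copies summed, so repeat copies alone leave the strand difference open. Neither value was adjusted for GC content.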
